A study of Mus musculus with 2 samples.

How the data were processed

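Whole-brain cells of 2-week-old mice were measured by single-cell RNA sequencing in 2 libraries, 1 from a wild-type brain and 1 from a Gba flox/flox; nestin-Cre brain, per the labels. The latter is called the mutant library. Nestin-Cre is a recombinase transgene active in neural progenitors, so that neurons and glia descended from them lose the floxed gene, and Gba encodes the lysosomal enzyme glucocerebrosidase, whose loss causes Gaucher disease. The labels do not say which exons are floxed. Per the labels' protocols, brains were dissociated with papain, myelin and debris were removed by centrifugation in Percoll, and libraries were made with the 10x Genomics Chromium 5' v2 kit.

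Each deposited file held UMI counts per gene and cell barcode with no normalization, made with Cell Ranger 6.0.0 against mm10, per the submitters' processing notes. The annotation release and the cell-calling settings were not stated. The files named genes by Ensembl ID. Of 32285 IDs, 32158 matched a symbol in the gene table, and gene positions were taken from GENCODE M21. Clec7a, Mx1, Gba3 and Cert1 were on the gene lists but had no matching ID and were not analysed here.

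Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept, which were 10815 of 13022 in wild type and 12454 of 14638 in the mutant library. Scrublet scored doublets within each library. Its own threshold called 4.55% and 5.19% of these barcodes, and the highest-scoring barcodes were removed at 0.8% per 1000 barcodes, 936 and 1241. This left 9879 wild-type and 11213 mutant cells. The cells of both libraries were clustered together after scaling to 10000 counts and log1p transformation, with 2000 variable genes chosen within libraries, 30 principal components, 15 neighbours and Leiden resolution 1 (Python 3.11.15, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9).

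The 34 clusters were named only from marker lists fixed before the data were examined. Each cluster's 10 leading genes, by fold over the cells outside its class, were checked for markers of its own and of other classes. An unnamed cluster was set against all other clusters. No cluster of a named class held more markers of another class than of its own. Set against all other clusters in place of the cells outside its class, cluster 7 led with cell cycle genes (2 neural progenitor markers, Mki67 and Top2a, and no microglia marker). In the same comparison cluster 12 led with immune genes such as Ccl12, Cfb and Ifi27l2a (1 monocyte marker, Plac8). Astrocyte-like cluster 3 led with Serpina3n, Timp1 and Lcn2 (1 Bergmann glia marker, A2m, and no astrocyte marker). By that comparison cluster 8, which held 84.5% and 84.6% of the neuroblast-like class, led with 4 neuron and 3 neuroblast markers. Microglia-like values are therefore also given for clusters by number. Cluster 24 held microglial genes. Set against all other clusters, the microglia-like ones among them, it led with Spp1, Gpnmb and chemokine genes. These held 1 T or NK cell marker (Ccl5) and no microglia marker. By that comparison clusters 7 and 12 held no microglia marker either, but they stayed microglia-like by the comparison with cells outside their class. Cluster 24 was first counted as microglia-like and was set unnamed on its leading genes after values had been seen. Clusters 13 (haemoglobin beside microglial genes), 19 (no marker of a list), 20 (a mixture of leukocyte genes), 22 (pericyte markers, with endothelial markers at a median of 84.1% of their endothelial-like level) and 25 (very high UMI counts, with endothelial genes) also stayed unnamed, and no cluster was named for oligodendrocyte precursors.

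In each class with at least 50 cells in each library, UMI counts were summed per library and divided by the class total and scaled to 1e6 (CPM), with exact Poisson 95% intervals. The log2 ratio is the mutant over the wild-type value with 10 CPM added to both, and CPM ratios without an added value carry exact conditional binomial 95% intervals. Shares of cells carry exact Clopper-Pearson 95% intervals, but a share of 0 is given with the limit that 3 cells of the total set. With 1 library per genotype there was no replicate, no test was run, and every interval covers counting error only. For each gene list, the median log2 ratio was taken over members with at least 30 CPM in either library, and its percentile was computed among 10000 random lists of the same size matched on mean expression. A gene with little RNA in wild type passes this filter only if it is high in the mutant library. This can raise the median of a list and the part of its members that is higher. In the same way, a gene with little RNA in the mutant library passes only if it is high in wild type. That can lower the median and raise the part that is lower. A list member counted as higher or lower at a ratio of at least 1.5-fold with intervals that did not overlap.

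Genes were named by a rule fixed in advance. They had at least 30 CPM and 20 UMIs in the library where they were higher, intervals that did not overlap, a ratio of at least 1.5-fold with 10 CPM added, and a level in the class of at least 0.5 times that over all other kept cells of that library. Mitochondrial, ribosomal protein, haemoglobin, Gm-numbered, Rik, Y-linked, immunoglobulin and T cell receptor genes, Xist and Tsix were left out. The 12 largest ratios in each direction were named in microglia-like cells and the 6 largest in each other class, with 2 to 4 members of each list, and Gba, Clec4e and Tnf in every class. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs.

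The gene rule, without its condition on other cells, was tested on simulated counts with 200 genes changed by known folds and with counting error alone. In simulated microglia-like cells, 98.5% of the genes changed 2-fold were recovered, and 9.86% of those changed 1.5-fold, over 5117 genes. In simulated neuron-like cells, the smallest class simulated, 90% of the genes changed 2-fold were recovered over 6240 genes. Alternatives varied the cell filter, doublet removal, clustering, scaling, removal of free RNA, the added CPM, the filter on list members, the thinning depth and, chosen after seeing the data, the clusters counted in the microglia-like and astrocyte-like classes.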

Results

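RNA of single brain cells was measured in 1 wild-type library and 1 Gba flox/flox; nestin-Cre library (the mutant library), so the comparison describes how the cells of these 2 brains differed, class by class. The wild-type file held 13022 barcodes with 92068834 UMIs, and the mutant file 14638 barcodes with 105344529 UMIs. After filtering, 9879 wild-type cells had a median of 5385 UMIs and 2367 genes, and 11213 mutant cells had 5649 UMIs and 2419 genes. Both libraries came from male animals by their RNA, since Ddx3y, a Y-linked gene, was at 47.1 and 37.6 CPM in microglia-like cells of the wild-type and the mutant library, and Xist, made from the inactive X chromosome, had 0 UMIs there in both. Paired values are given with the wild-type library first. With no replicate, genotype cannot be separated from animal, dissociation or library, and every interval given covers counting error only.

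Gba (ENSMUSG00000028048, chromosome 3, 89202928 to 89208966, plus strand, mm10), the targeted gene, was lower in the mutant library in all 12 cell classes. It was at 43.4 CPM (40.3 to 46.8) in wild-type and 9.38 CPM (8.15 to 10.7) in mutant astrocyte-like cells, and at 88.2 and 20.5 CPM in oligodendrocyte-like cells, which gave ratios of 0.216 (0.184 to 0.252) and 0.233 (0.189 to 0.285). Neural progenitor-like cells had 15.2 and 3.38 CPM (ratio 0.223 (0.106 to 0.424)), neuroblast-like cells 20.3 and 11 CPM (0.54 (0.335 to 0.848)) and neuron-like cells 24.1 and 13 CPM (0.539 (0.302 to 0.959)). Classes that do not descend from neural progenitors were lower too, at a ratio of 0.247 (0.113 to 0.489) in pericyte or smooth muscle-like cells and 0.543 (0.315 to 0.915) in fibroblast-like cells. The ratio was 0.636 (0.589 to 0.686) in microglia-like cells (93.7 and 59.6 CPM), 0.45 (0.334 to 0.60) in border-associated macrophage-like cells (98 and 44.1 CPM) and 0.40 (0.347 to 0.461) in endothelial-like cells (44 and 17.6 CPM). In the microglia-like clusters 6 and 11, which held many cells of both libraries, the ratio was 0.544 (0.489 to 0.604). The interval of the ratio reached above 1 in ependymal-like cells, with an upper bound of 1.02, and in choroid plexus-like cells, with an upper bound of 1.44, so no difference was detectable there at this depth. The labels do not name the floxed exons, so reads from outside the deleted part may be counted, and the residual level does not measure intact Gba. Mtx1, which lies beside Gba, was at 42.8 and 51.2 CPM in microglia-like cells. Nes, the nestin gene, was at 206 and 122 CPM over all kept cells outside the microglia-like class. It was at 7.27 and 8.03 CPM in astrocyte-like, 33.9 and 29.3 CPM in neuroblast-like and 93.8 and 84.4 CPM in neural progenitor-like cells. Most Nes RNA thus lay in other classes, and whether lower Gba follows Nes in vessel and membrane cells was not tested.

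**Figure D1:**
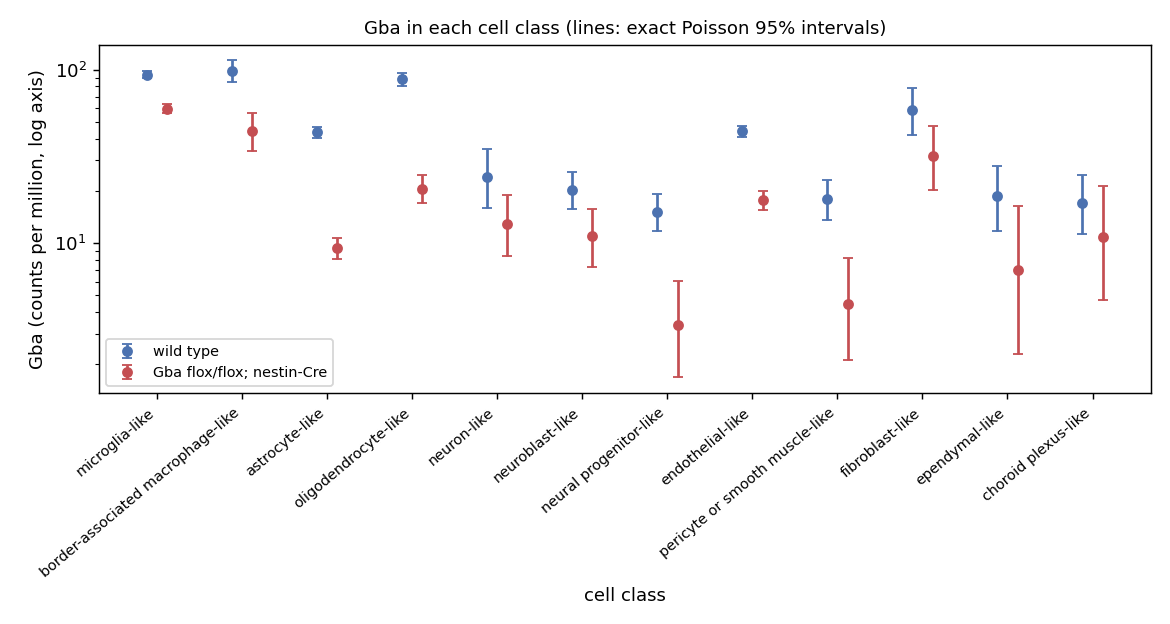
Gba level (CPM, vertical log axis) in each of the 12 cell classes (horizontal axis), with blue points for the wild-type and red points for the mutant library and lines for exact Poisson 95% intervals that cover counting error only (1 library each). The mutant value lies below the wild-type value in every class, with the intervals apart in astrocyte-like cells at 43.4 and 9.38 CPM.

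Both libraries held the same 12 classes of cells. Microglia-like cells, the brain's resident macrophages, were 33.3% (32.4 to 34.3%) of wild-type and 33.1% (32.2 to 34%) of mutant cells, astrocyte-like cells 26.9% and 27.8%, and endothelial-like cells 12.1% and 11.3%. Cluster 24, which held microglial genes but was set unnamed on its leading genes after values had been seen, was 0.192% (0.116 to 0.30%) of wild-type and 6.22% (5.78 to 6.69%) of mutant cells. Counted with the microglia-like class, it brought the mutant share to 39.3%. Border-associated macrophage-like cells were 2.97% (2.64 to 3.32%) and 2.0% (1.75 to 2.27%), and choroid plexus-like cells 1.29% (1.07 to 1.53%) and 0.624% (0.487 to 0.788%). Neurons were few, 0.607% and 0.963%, in this dissociated material. The cell filter and doublet removal moved these shares, and the effect of dissociation was not measured. Under the stricter cell filter astrocyte-like cells were 14.7% and 18.9%, and with 2 times as many doublets removed neuron-like cells were 0.19% and 0.0501%.

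**Figure D2:**
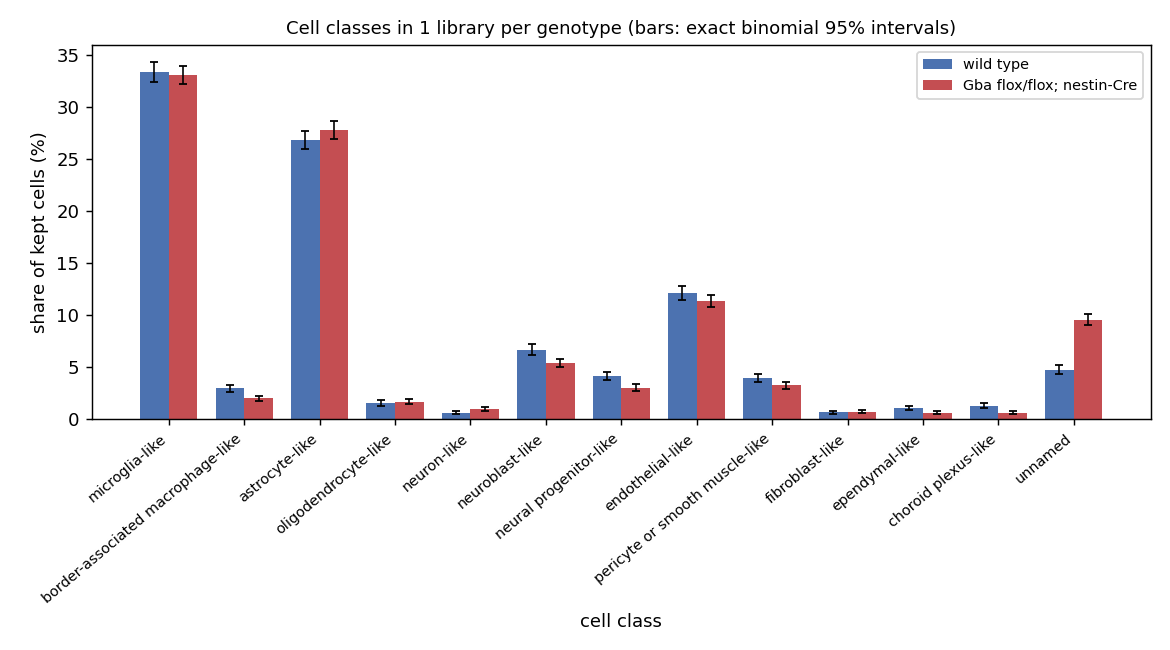
Share of kept cells (percent, vertical axis) in each cell class (horizontal axis), with blue bars for the wild-type and red bars for the mutant library and lines for exact Clopper-Pearson 95% intervals that cover counting error only (1 library each). The microglia-like shares overlap at 33.3% and 33.1%, while cells in unnamed clusters were 4.77% and 9.56%.

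Microglia-like cells of the mutant library had more RNA of interferon and disease-associated genes and less of homeostatic genes. The median log2 ratio of all genes in this class was -0.08, and list medians here are given relative to it. Of 23 measured type I interferon response genes 22 were higher and 0 lower, with a median of 2.79 (percentile 100 among random lists). Ifitm3, which blocks virus entry, was at 24.3 CPM (21.9 to 26.8) in wild type and 1097 CPM (1083 to 1111) in the mutant library, Irf7, a transcription factor of interferon genes, at 8.65 and 336 CPM, and Isg15, a ubiquitin-like protein, at 11.1 and 332 CPM. Of 23 disease-associated microglia genes 17 were higher and 0 lower (median 1.10). Spp1, a secreted phosphoprotein, was at 3.64 and 170.0 CPM, Cst7, a protease inhibitor, at 12.4 and 177 CPM, and Axl, a receptor for dying cells, at 9.33 and 103 CPM. Of 20 homeostatic genes 0 were higher and 9 lower (median -0.43), among them P2ry12, a receptor for ADP (7264 and 2967 CPM), P2ry13 (608 and 265 CPM) and the fructose transporter gene Slc2a5 (307 and 142 CPM).

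Other named genes that were higher in microglia-like cells were the chemokine genes Cxcl10 (1.73 and 372 CPM), Ccl5 (0.679 and 189 CPM), Ccl12 (91.7 and 1261 CPM) and Ccl2 (13.2 and 229.7 CPM), the interferon-induced Ifi27l2a (38.8 and 770.5 CPM) and Oasl2 (7.78 and 190.2 CPM), complement factor B, Cfb (3.58 and 144 CPM), and the class I gene H2-Q7 (1.79 and 124 CPM). Named genes that were lower also included Gpr165 (204 and 58.8 CPM), Sema4b (80.7 and 25 CPM), the transcription factor gene Maf (495 and 212 CPM), and Dusp6, a phosphatase that acts on ERK (273 and 118 CPM). The remaining ones, Klhdc8b, Tnfrsf17, Med12l, Mdfi and Abca9, had log2 ratios from -1.16 to -1.06.

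Of 14 antigen presentation genes 10 were higher in microglia-like cells (median 1.26), led by class I genes such as H2-K1 (248 and 1496 CPM). Among 21 inflammatory cytokine and NF-kB target genes 12 were higher and 1 lower (median 0.97). Over members at 100 CPM the median of this list, not relative to all genes, was 1.58, against 0.89 on the same basis over members at 30 CPM. Glycolysis genes were higher in 9 of 14 cases (median 0.84), such as Ldha, lactate dehydrogenase (188 and 484 CPM), and Gapdh (382 and 917 CPM). Cell cycle genes were higher in 25 of 27 (median 1.32), with Ube2c at 63.6 and 238 CPM and Top2a at 58.2 and 202 CPM. Nuclear oxidative phosphorylation genes had a median of 0.48, with 2 of 27 past 1.5-fold, and of 0.21 in clusters 6 and 11 together and 0.06 and 0.08 in each singly. Lysosome genes had a median of 0.12 (percentile 87.7, with 6 higher and 1 lower of 46), although the protease genes Ctsc (266 and 652 CPM) and Ctsz (1234 and 2673.5 CPM) were higher. Medians were 0.07 for complement and phagocytosis, -0.03 for glycosphingolipid metabolism, the pathway of the Gba substrate, and 0.03 for cholesterol synthesis.

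Mincle receptor pathway genes, which include receptors for glycolipids, had a median of -0.15 in microglia-like cells (percentile 11), with 0 higher and 1 lower of 11, and of -0.01 in clusters 6 and 11. Not relative to all genes, the class median was -0.23, against -0.15 after median ratio scaling and -0.09 over members at 100 CPM. Clec4e, which encodes Mincle, had 0 UMIs in this class in both libraries, which allows a share of cells with a UMI of up to 0.0911% in wild type and 0.0809% in the mutant library (3 cells of the total). Outside the named classes, Clec4e had 8 and 29 UMIs (21 and 49 CPM) in the leukocyte cluster 20 and 0 and 1 in cluster 24. Tnf, an inflammatory cytokine, was at 6.24 and 33.7 CPM in this class, a ratio of 5.41 (4.38 to 6.73). After thinning to 1000 UMIs, with 0 cells left out, 0.607% of wild-type and 2.18% of mutant microglia-like cells had a Tnf UMI. Unthinned, the shares were 2.67% and 7.9%. Endothelial-like cells, which should lack Tnf, had 0% in both libraries after thinning, which allows up to 0.251% and 0.236%. The median depths in wild type and the mutant library were 4645 and 4710 UMIs in microglia-like cells and 12201.5 and 9849.5 in endothelial-like cells. In clusters 6 and 11 alone Tnf went the other way, at 5.6 and 3.24 CPM. Cluster 7 had 13.2 CPM (7.84 to 20.9) in wild type and 52.5 CPM (46.9 to 58.5) in the mutant library.

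**Figure D3:**
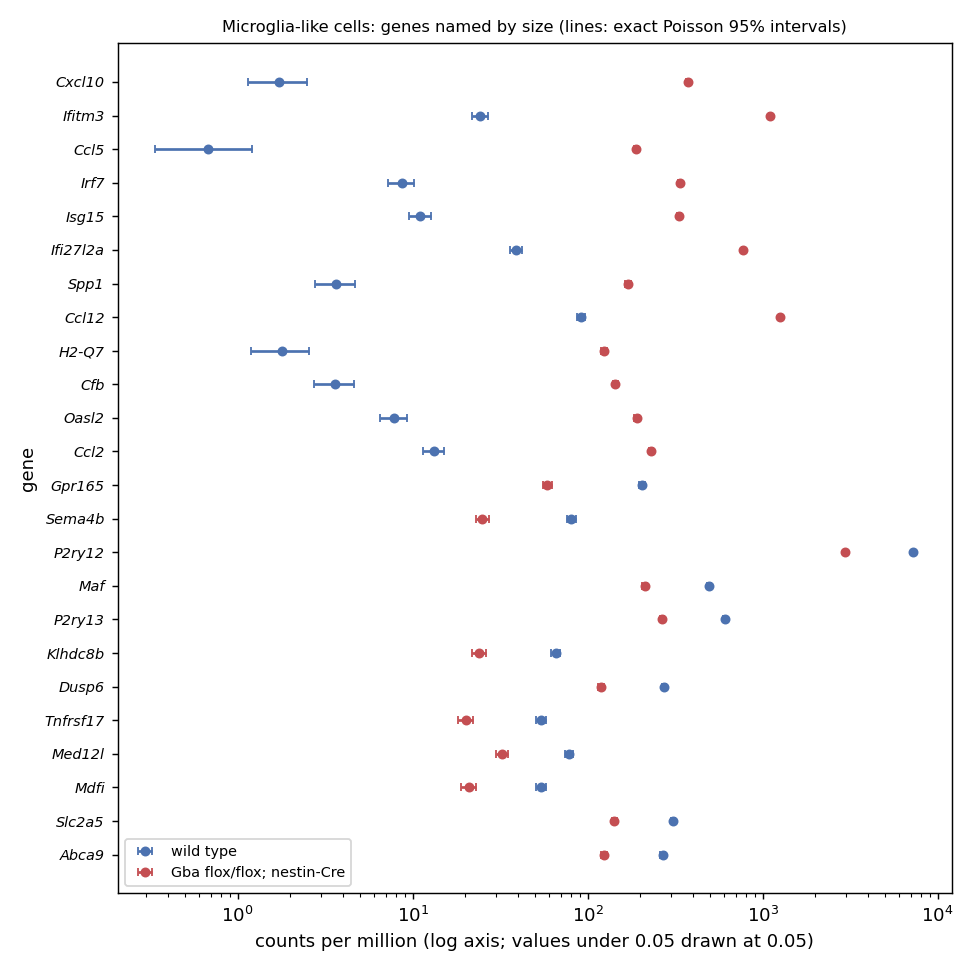
Levels (CPM, horizontal log axis) of the genes named by size in microglia-like cells (vertical axis), with blue points for the wild-type and red points for the mutant library and lines for exact Poisson 95% intervals that cover counting error only (1 library each). The mutant value is higher for genes such as Cxcl10 (1.73 and 372 CPM) and lower for genes such as P2ry12 (7264 and 2967 CPM).

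Different clusters held most of the microglia-like class in each library. Cluster 6 held 82% of the class in wild type and 23% in the mutant library, cluster 11 11.8% and 32.2%, cluster 7 6.04% and 20.4%, and cluster 12 0.152% and 24.4%. A cluster made almost entirely of 1 library, such as 12, may stand for that library and not for a cell type. Within clusters 6 and 11 together, the median log2 ratio relative to all genes was 1.91 for interferon genes, 0.60 for antigen presentation, 0.39 for disease-associated genes, -0.14 for homeostatic genes, 0.35 for glycolysis, 0.16 for inflammatory genes and 0.33 for the cell cycle. Fewer members reached 30 CPM there than in the class, with 6 cell cycle, 15 inflammatory and 17 disease-associated genes. Medians of these lists in clusters and in the class thus cover different genes. In cluster 11 alone, interferon genes had a median of 1.39, while disease-associated (0.06) and homeostatic genes (0.02) lay within the middle 95% of random lists. Cluster 6 alone had 1.71, 0.21 and -0.03 for these lists. Cells were clustered by their RNA, and cluster 6 led with homeostatic genes such as P2ry12 and P2ry13. Cells that differ in such genes can thus fall into other clusters. A small median within a cluster does not show that these genes were unchanged. Cluster 7, with 199 wild-type and 757 mutant cells, had 2.87, 1.39 and -0.44, with inflammatory genes at 1.13 and cell cycle genes, with which it led, at -0.10. Lysosome genes were at 0.13 in clusters 6 and 11 together, at 0.32 in cluster 7, at 0.11 in cluster 6 alone and at 0.28 with cluster 24 counted in the class, all above the middle 95% of random lists, but at 0.01 in cluster 11 alone, within it. The mix of clusters 6 and 11 differed between the libraries. In cluster 6 and cluster 11 taken singly, medians were -0.09 and -0.03 for inflammatory genes, of the other sign than together, 0.14 and 0.08 for glycolysis, 0.47 and 0.54 for antigen presentation and 0 (rounded) and 0.22 for the cell cycle. With cluster 24 counted in the class, the disease-associated median was 1.97 and the glycolysis median 1.41 on this basis. With 1 CPM added in place of 10, the interferon median of the class was 4.09, against 2.71 with 10, neither relative to all genes.

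Border-associated macrophage-like cells, the macrophages of brain membranes and vessels, shared the interferon pattern. Of 26 interferon genes 25 were higher and 0 lower in the mutant library (median log2 ratio 1.45), with Irf7 at 51.1 and 513 CPM, Ifit2 at 13.3 and 156 CPM and Cxcl10 at 4.08 and 176 CPM. Antigen presentation genes were higher in 9 of 14 and lower in 1 (median 0.78), and inflammatory genes had a median of 0.43. Immediate early and dissociation response genes were lower in 6 of 21 and higher in 1 (median -0.26), with Fos at 90.4 and 11 CPM. Retnla, a secreted protein of alternatively activated macrophages, was at 2626 and 1151 CPM, and the lectin gene Cd209d at 47.5 and 0.689 CPM, a ratio of 0.0145 (0.000364 to 0.0829). Lysosome, complement and cell cycle medians were 0.00, 0.04 and 0.12, and Clec4e had 0 UMIs in both libraries. Microglia markers were higher in 3 of 17 and lower in 1 (median 0.07, percentile 97.8). The markers of the class itself had a median of -0.30 (percentile 0), with 11 of 11 past neither limit. Free RNA from microglia was not tested in this class.

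Astrocyte-like cells of the mutant library had more RNA of interferon and reactive genes and less of cholesterol synthesis genes. Interferon genes were higher in 16 of 16 (median log2 ratio 2.60, 4.18 with 1 CPM added), with Isg15 at 1.91 and 220.5 CPM, Ifit3 at 4.68 and 131 CPM and Lgals3bp at 48.3 and 379 CPM. Reactive astrocyte genes were higher in 12 of 18 (median 1.23), among them Cxcl10 (0.924 and 230.4 CPM) and the interferon-inducible Gbp3 (5.73 and 57.2 CPM), and antigen presentation genes in 8 of 8 (median 1.66). The reactive list shares H2-T23, H2-D1 and Psmb8 with the antigen presentation list, so these results are not independent. Cholesterol synthesis and sterol transport genes were lower in 7 of 23 and higher in 0 (median -0.52, percentile 0), with Fdps, a synthase of farnesyl diphosphate, at 361 and 199 CPM, Dhcr7, which makes cholesterol from its last precursor, at 173 and 94.3 CPM, and Hmgcr, the rate-limiting reductase, at 324 and 204 CPM. Inka2 (35.8 and 11 CPM), Olig2, a glial transcription factor (74.6 and 30 CPM), and Sez6l (92.5 and 49.1 CPM) were lower. Markers of oligodendrocyte precursors had a median of -0.43 in astrocyte-like cells (percentile 0) and those of microglia 0.38. Genes of astrocyte homeostasis had a median of -0.03, with 20 of 20 past neither limit. Cluster 3, which held 0 wild-type and 174 mutant cells and led with reactive genes such as Serpina3n and Lcn2, carried part of this. Without it the reactive median was 0.34 and the antigen presentation median 0.86, and under the stricter cell filter the reactive median was 0.74. The mix of other astrocyte-like clusters also differed, with cluster 1 at 38.9% and 27.2% of the class and cluster 0 at 28.3% and 33.6%. Whether the cholesterol difference follows this mix was not tested.

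Oligodendrocyte-like cells, which make myelin, had 7 of 8 interferon genes higher (median log2 ratio 2.00), with Stat1 at 14.5 and 105 CPM and Usp18, a regulator of interferon signalling, at 2.96 and 38.1 CPM. Over members at 5 CPM, 18 of 19 were higher in this class (median 1.65). Microglia markers were higher there in 3 of 10 (median 0.38). Cholesterol genes were lower in 2 and higher in 1 of 24 (median -0.32), with Mvd at 227 and 140.3 CPM and Lss at 244 and 156 CPM. Myelin and maturation genes had a median of 0.03, with none of 25 past 1.5-fold. In neuron-like cells 8 of 8 interferon genes were higher (median 2.41), with Isg15 at 5.35 and 189.7 CPM, and Npas4, an activity-regulated transcription factor, was at 50.9 and 12.5 CPM. Microglia markers in these cells were higher in 6 of 12 (median 0.59) and astrocyte markers in 3 of 7 (median 0.44). The interferon median of neuron-like cells was 1.52 as a mean over cells and 1.48 over members at 5 CPM, of which 20 of 25 were higher. Such genes pass the 30 CPM filter mainly through the mutant library where, like Isg15, they are low in wild type. The synapse list median of -0.09 turned positive under the stricter cell filter (0.052) and with no doublets removed (0.087). Neuron-like cells numbered 60 and 108, and in their cluster 32 the median depth was 6174.5 UMIs in wild type and 26891.5 in the mutant library. With 1 CPM added, the interferon medians were 3.56 in oligodendrocyte-like and 4.81 in neuron-like cells. Neuroblast-like and neural progenitor-like cells had cholesterol medians of -0.22 and -0.21 and cell cycle medians of 0.13 and 0.03. The progenitor cholesterol median was -0.10 with no doublets removed and -0.36 with each library clustered separately. Ifi27 was higher in both, at 21.2 and 79 CPM and 22.6 and 130.1 CPM, and in progenitor-like cells the transcription factor genes Gsx1 (111 and 38.7 CPM), Olig2 (154 and 88.7 CPM) and Egr1 (52.7 and 11.1 CPM) were lower, with oligodendrocyte precursor markers at a median of -0.39 (percentile 0).

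Cells of vessels and membranes carried the interferon pattern as well. Endothelial-like cells had 21 of 22 interferon genes higher in the mutant library (median log2 ratio 1.69), with Ifit3 at 2.66 and 133 CPM and Irf7 at 45.7 and 429 CPM, and 9 of 10 antigen presentation genes higher (median 1.20). Blood-brain barrier genes had a median of 0.02 and endothelial activation genes 0.25. Immediate early genes were lower in 3 and higher in 1 of 23 (median -0.40), and Ccn1, a matrix protein gene, was at 187 and 72.7 CPM. In pericyte or smooth muscle-like cells 18 of 18 interferon genes were higher (median 1.84), and over members at 5 CPM 24 of 25 (median 1.39). Cell cycle genes were lower there in 17 of 19 (median -1.72), with Ube2c at 86.3 and 2.67 CPM and Mki67, a marker of dividing cells, at 82.9 and 4.44 CPM, and the median was -0.76 with no doublets removed. Ube2c and Mki67 passed the 30 CPM filter only through the wild-type library, and such members push the median and the count down. How many of the 391 wild-type and 367 mutant cells of this class carried this RNA was not counted. Fos (98.6 and 11.6 CPM) and Egr1 (583 and 116 CPM) were lower in a list of immediate early genes with 11 of 25 lower (median -0.46). Fibroblast-like cells had 14 of 17 interferon genes higher (median 1.66), and over members at 5 CPM 14 of 21 (median 1.59). Microglia markers were at 0.43 there and 0.24 in pericyte or smooth muscle-like cells. In fibroblast-like cells Rbp4, a retinol carrier, was at 145 and 3.96 CPM, a ratio of 0.0273 (0.00554 to 0.0819), and Pi16 at 230.5 and 15.8 CPM.

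Ependymal-like and choroid plexus-like cells, which line and feed the ventricles, had fewer than 5 interferon genes at 30 CPM, as had neuroblast-like and neural progenitor-like cells. Over members at 5 CPM the interferon medians were 0.12 in ependymal-like and 0.31 in choroid plexus-like cells, 0.91 in neuroblast-like and 0.93 in neural progenitor-like cells, against 2.30 in astrocyte-like cells. Microglia markers had medians of -0.52, -0.38, 1.12 (7 of 8 higher) and -0.62 in the same 4 classes, and endothelial markers 0.75 in choroid plexus-like cells. Ependymal-like cells had lower endoplasmic reticulum and integrated stress response genes in 3 of 17 (median -0.37, -0.21 with no doublets removed), with the chaperone gene Hspa5 at 705 and 424 CPM. Sspo, a glycoprotein secreted by the subcommissural organ, was at 134 and 7.05 CPM. In choroid plexus-like cells Apoc1, an apolipoprotein gene, was at 77.7 and 24.5 CPM, and cholesterol genes had a median of -0.03. These classes held 68 and 70 mutant cells.

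**Figure D4:**
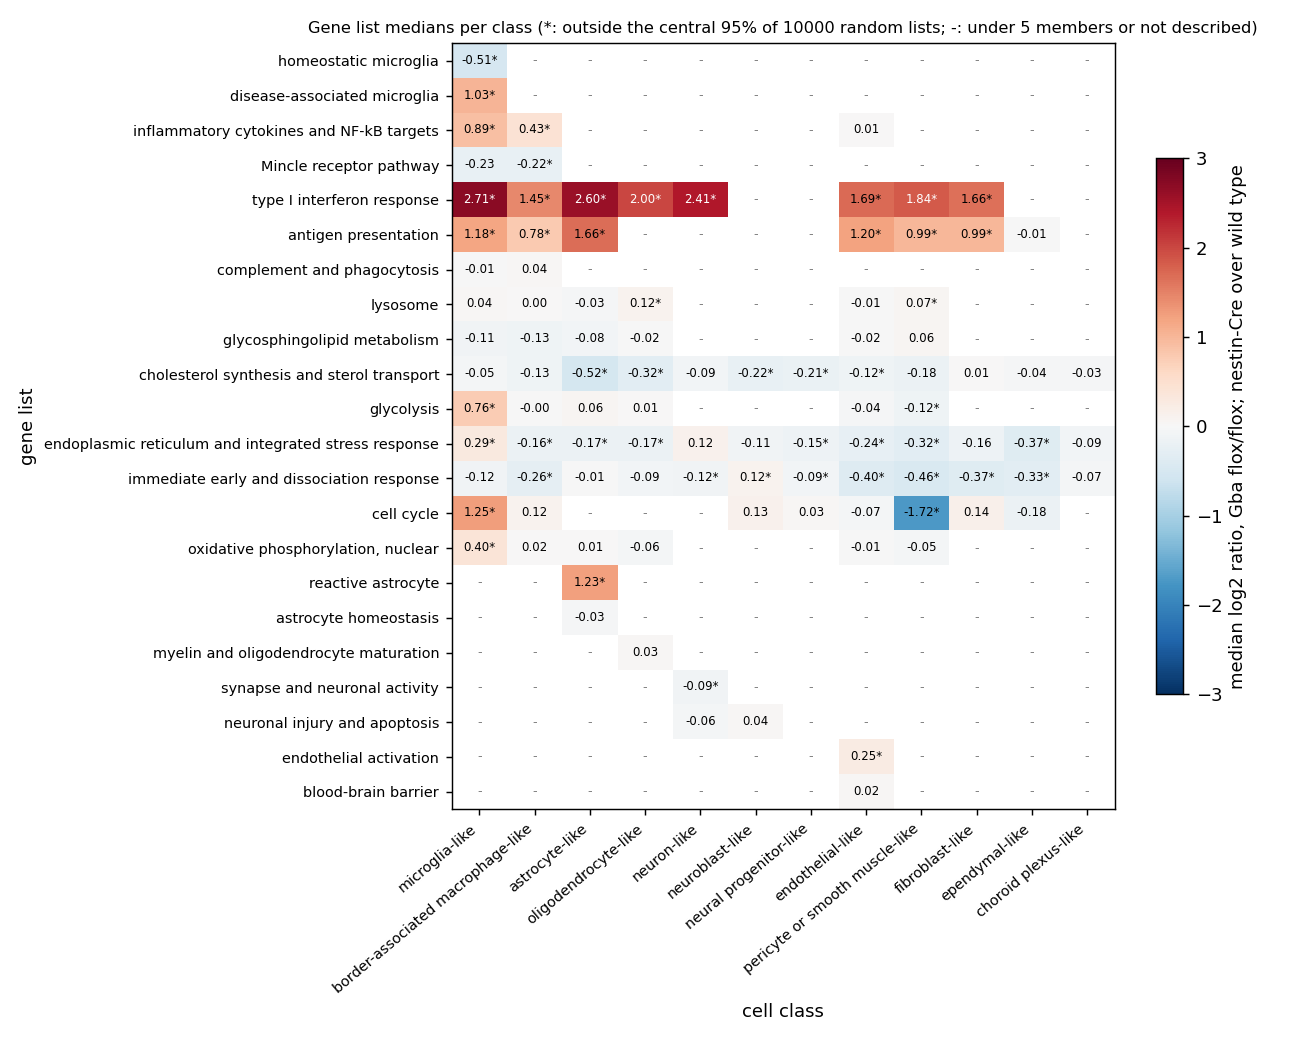
Median log2 ratio (mutant over wild-type library, 10 CPM added, colour scale) of each described gene list (vertical axis) in each cell class (horizontal axis), 1 library each, not relative to the median of all genes. An asterisk marks a median outside the central 95% of 10000 random lists, and a dash a list with under 5 measured members or not described in that class. Interferon genes are higher in every class drawn for that list, from 1.45 in border-associated macrophage-like to 2.71 in microglia-like cells, and the lowest cell cycle value is -1.72 in pericyte or smooth muscle-like cells.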

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

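The tests of free RNA, of doublets and of the animal or preparation were set down before their results were seen. Those of scaling, monocyte-derived cells, dissociation, recombination tied to Nes, Mtx1 and the floxed allele, and of free RNA in classes other than astrocyte-like and endothelial-like cells, were chosen only after, and the measures used for scaling, monocyte-derived cells, dissociation, Nes and Mtx1 were changed after a first run.

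Cells in 2 of the 6 clusters that the comparisons do not use were more frequent in the mutant library than the wild-type interval allows, and those in 3 less frequent. Cluster 24 held 6.22% of mutant cells (698 cells), above the wild-type 0.192% (0.116 to 0.30%). In the mutant library this cluster had Hexb at 7674 CPM and C1qa at 9187 CPM, both microglial genes, with Cd3e, a T cell gene, at 0 UMIs and Ccr2, a monocyte gene, at 0.631 CPM, but Ms4a7, a macrophage gene, at 126 CPM (5.05 in cluster 12 and 0 in cluster 6). Cluster 20, a mixture of leukocytes, held 1.05% of mutant cells, above the wild-type 0.668% (0.517 to 0.849%). Clusters 13 (1.68% against 2.79%, 2.48 to 3.14%), 25 (0.0713% against 0.476%, 0.35 to 0.632%) and 19 (0.169% against 0.304%, 0.205 to 0.433%) lay below their wild-type intervals. The mutant interval of cluster 19 (0.102 to 0.264%) overlapped the wild-type one, so no difference was detectable there. All these values come from 1 library per genotype with intervals that cover counting error only.

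Interferon genes were higher in the mutant library outside microglia-like cells too. Free RNA from microglia would have brought at most 2.27% of the list's increase in astrocyte-like or endothelial-like cells (3.27% with cluster 24 counted as microglia-like), under the 25% set as the bound. In the other classes outside macrophages it would have brought 13.2% (oligodendrocyte-like), 21.5% (neural progenitor-like), 2.74% (pericyte or smooth muscle-like) and 5.52% (fibroblast-like), but 33.3% in neuron-like and 47% in neuroblast-like cells, where it stays open, and 160.3% and 191% in ependymal-like and choroid plexus-like cells, where it could account for the whole increase. After median ratio scaling the lower of the 2 list medians was 1.72, which argues against scaling as the cause. The genotype may account for the pattern, but with 1 library per genotype it cannot be told apart from the animal or the preparation.

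Homeostatic genes were lower and disease-associated genes higher in mutant microglia-like cells. In clusters 12 and 24 together, 8 microglial markers stood above their level in border-associated macrophage-like cells by a lower quartile of 3.57 times. Cluster 12 was named microglia-like on leading genes that include Hexb, Tmem119, Olfml3 and Siglech, so their excess there was set by the naming. Of the other markers, P2ry12 was at 1499 CPM in mutant cells of cluster 12, against 239 CPM in mutant border-associated macrophage-like cells. Sall1 was at 157 against 8.96 CPM, Gpr34 at 578 against 130 CPM and Fcrls at 1603 against 1348 CPM. Apart from Fcrls, these argue against monocyte-derived cells in cluster 12, as far as such cells lack these markers. In cluster 24 alone the markers ran from 1.11 times (Fcrls) and 1.86 times (P2ry12) to 18.4 times (Olfml3). These lower values and Ms4a7 make the argument less sure for cluster 24. Markers of astrocyte-like, endothelial-like, neuron-like and oligodendrocyte-like cells were also taken in clusters 12 and 24. The highest of the 4 median levels was 0.313% of that in their own class, which argues against doublets with these classes. Doublets with other cells were not tested. The upper quartile of the dissociation list was 0.32, under the bound of 0.5. This argues against a stronger response to dissociation in the class without cluster 24, only as far as this list measures it. With cluster 24 counted it was 0.57, so such a response stays open there. A microglial response to the genotype may account for the pattern and was not separable from the animal or the preparation.

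Gba was lower in microglia-like and border-associated macrophage-like cells, which do not descend from neural progenitors. Their ratios had upper bounds of at most 0.686 (0.777 for microglia-like cells with cluster 24), although Nes had 1 and 0 UMIs in border-associated macrophage-like cells, which argues against recombination tied to Nes in that class. Nes was at 18.7 and 69.8 CPM in microglia-like cells, so the test decides nothing there, and Nes RNA at sampling does not show where the transgene was active before. The lower bound of the Mtx1 ratio was at least 1.31 times the upper bound of the Gba ratio, which argues against scaling. A floxed allele that yields fewer reads without recombination could also account for it and stays open, since the highest upper bound of the Gba ratio over the classes was 1.44, as do the genotype and the animal.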

How the results depend on the processing

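The alternatives that counted only clusters 6 and 11, left out cluster 3, or counted cluster 13 or 24 as microglia-like were chosen after seeing the data, and all others were planned. For the microglia-like, astrocyte-like and endothelial-like shares and the leading list and Gba values, 75 values moved, 58 did not and none changed sign. Of the other values, 805 moved, 2755 did not and 10 changed sign. A share counted as moved outside its 95% interval, a list median when it differed by over 1 SD of the random lists' medians, and a gene's log2 ratio when it differed by over 0.5 times the log2 width of its ratio's 95% interval (9 where that is open), so an unmoved value near 0 can differ by over 1.5 times. The cause was not tested for any of these changes, except where the setting itself changes which cells or genes are counted. After a first run over all lists and classes, the pairs described were narrowed. Of 110 pairs not described, 20 had a change of sign under some setting (29 of 1012 values), against 2 of 100 pairs described (3 of 979 values). The narrowing went by list and class, after these changes of sign had been seen, so pairs without a change of sign were left out too. Few cells stood behind small classes, 60 and 108 in the neuron-like class. Shares below give the wild-type value first.

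With the looser cell filter, shares were 29.7% and 25.9% (microglia-like), 32.9% and 30.9% (astrocyte-like) and 11.2% (endothelial-like, wild type), and microglia-like medians were -0.41 (homeostatic), 0.83 (disease-associated) and 2.49 (interferon). The stricter filter gave shares of 39.6% and 31.9%, 14.7% and 18.9%, and 15.1% and 13.8%, microglia-like medians of -0.42, 0.87 and 2.5, interferon medians of 2.35 (astrocyte-like) and 1.73 (endothelial-like), and an astrocyte-like cholesterol median of -0.42. With no doublets removed, shares were 31.4% and 27.5%, 25.3% and 26.3%, and 13.5% and 13%, the disease-associated median was 0.85, and interferon medians were 2.57 (microglia-like) and 1.79 (endothelial-like). With 2 times as many doublets removed, shares were 36.6% (microglia-like, mutant), 29.9% and 29.3% (astrocyte-like), and 13.4% and 12% (endothelial-like).

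The microglia-like share was 34.6% (mutant) at Leiden resolution 2 and 35.3% and 31.4% at 0.5. With each library clustered separately, shares were 36.3% and 36.2% (microglia-like), 28.7% (astrocyte-like, mutant) and 12.9% (endothelial-like, wild type), and microglia-like medians were 0.93 (disease-associated) and 2.91 (interferon). Counting cluster 13 gave microglia-like shares of 36.1% and 34.8%. Counting cluster 24 gave 39.3% (mutant), medians of -0.75 (homeostatic), 1.85 (disease-associated) and 3.0 (interferon), and a Gba log2 ratio of -0.41. Clusters 6 and 11 alone gave -0.20, 0.33 and 1.85, and a Gba log2 ratio of -0.77. Without cluster 3, astrocyte-like medians were 2.39 (interferon) and -0.48 (cholesterol).

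Median ratio scaling gave -0.41 (homeostatic), 1.11 (disease-associated) and 2.80 (interferon) in microglia-like cells, and 2.55 (interferon) and -0.48 (cholesterol) in astrocyte-like cells. As a mean over cells, the medians were 0.69 and 2.60 (disease-associated and interferon, microglia-like) and 2.27 and -0.45 (interferon and cholesterol, astrocyte-like). Removing 5% free RNA gave an astrocyte-like interferon median of 2.53. With 1 CPM added, interferon medians were 4.09 (microglia-like), 4.18 (astrocyte-like) and 2.05 (endothelial-like), and the astrocyte-like Gba log2 ratio was -2.10. With list members at 5 CPM, interferon medians were 2.30 (astrocyte-like) and 1.64 (endothelial-like). With members at 100 CPM, medians were 0.72 (disease-associated), 2.93 (interferon, microglia-like) and 3.31 (interferon, astrocyte-like).

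These values changed sign. In neuron-like cells the synapse list median was 0.052 (stricter filter) and 0.087 (no doublets removed), Ifitm3 was -0.81 (stricter filter) and Ecel1 -0.12 (no doublets removed). The lysosome median in pericyte or smooth muscle-like cells was -0.014 (looser filter), and Tnf in microglia-like clusters 6 and 11 was -0.24. With no doublets removed, Hexb was -0.015 in border-associated macrophage-like, Psat1 0.079 in fibroblast-like and Wfdc2 1.17 in ependymal-like cells. Nefh in choroid plexus-like cells was -0.11 as a mean over cells. All are log2 ratios, and the cause was not tested.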

Other observations

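The genes described here, apart from the lists, were chosen only after their values were seen. Ifnb1, which encodes interferon beta, had 163 UMIs (20.6 CPM) in cluster 24 of the mutant library and 0 in the 19 wild-type cells of that cluster. Microglia-like cells had 3 UMIs of it in wild type and 1 in the mutant library. Ifna2 and Ifna4, which encode alpha interferons, had 0 UMIs in mutant microglia-like cells. Tnf was at 122 CPM in mutant cells of cluster 24 and at 66.2 CPM in those of cluster 12. Among the 66 wild-type and 118 mutant leukocytes of cluster 20, cells with at least 4 T or NK cell markers numbered 20 in wild type and 33 in the mutant library, those with monocyte markers 10 and 20, B cell markers 15 and 17, and neutrophil markers 7 and 2.

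Endoplasmic reticulum and integrated stress response genes had a higher median in mutant microglia-like cells (log2 ratio 0.29, 5 of 18 higher) and lower medians in endothelial-like (-0.24), pericyte or smooth muscle-like (-0.32), astrocyte-like (-0.17) and oligodendrocyte-like cells (-0.17). The chaperone gene Hspa5 was at 511 and 346 CPM in astrocyte-like and 357 and 255 CPM in endothelial-like cells. The median was -0.13 in endothelial-like cells over members at 5 CPM and -0.16 in pericyte or smooth muscle-like cells with no doublets removed. In clusters 6 and 11 together the microglial median of this list was 0.06, not relative to all genes. On that basis it was -0.06 in cluster 6 (percentile 27.4 among random lists), -0.02 in cluster 11 (percentile 43.8) and 0.23 in cluster 7 (percentile 99.9). Relative to all genes, the medians were 0.12 in clusters 6 and 11 together, -0.01 in cluster 6, 0.01 in cluster 11 and 0.37 in cluster 7. Immediate early and dissociation response genes were lower in fibroblast-like cells in 6 of 24 (median -0.37), with Egr1 at 466 and 141 CPM, and had a median of -0.12 in microglia-like cells. Mki67 was seen in 2.88% of wild-type and 7.9% of mutant microglia-like cells after thinning to 1000 UMIs, with 0 cells left out, and in 4.8% and 17.4% unthinned. Astrocyte-like cells had 0.151% and 0.0642% after thinning, at median depths of 4499 and 5656 UMIs, against 4645 and 4710 in microglia-like cells.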
